A study of Homo sapiens and Mus musculus with 26 samples.

How the data were processed

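Per the file headers and file names, the authors deposited 5 tables of raw counts per gene, as fragments for the K562 and thymocyte tables and as reads for the HEL and CCRF-CEM tables, with no normalization. The values are whole numbers with different totals per library. Per the submitters' processing notes, fastp 0.13.1, HISAT2 2.1.0 and featureCounts 1.6.1 were used with the builds hg38 and mm10, with no role or settings recorded. The tables carry the exon coordinates and symbols of 28103 genes (K562), 28131 genes (HEL and CCRF-CEM) and 24984 genes (thymocytes), and coordinates given here are theirs. Per the labels' protocols, RNA was captured with oligo-dT beads and the libraries were made with a dUTP second strand, which marks the strand. The strand setting of the counting and the treatment of reads that map to several places are not stated, so counts of overlapping, antisense and near-identical genes (histones, ribosomal proteins, HSPA1A and HSPA1B, NBPF and TUBA3 genes) are uncertain. Among named genes, exons of RAP1GAP2, FDPS, SNHG7, ZFAS1, IER3, CA3, COL3A1, H19, FANCI, ATM, PDIA6, RPS3A, ENC1, STARD4, HMMR, NOP56, SLC7A11, SHMT2, WIPI1, PLAU, TNXB and CDKN1A overlap exons of other genes. No per-sample column of the deposited counts was left unused.

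The following was computed from the deposited counts in R 4.3.3, with choices made before the data were examined unless said otherwise. Each comparison was fitted on its own libraries with edgeR 4.0.16 (filterByExpr, TMM, quasi-likelihood F test with robust dispersions), and genes with a Benjamini-Hochberg adjusted p under 0.05 were called. The standard error of a log2 fold change is approximate, from the F statistic. CPM values are scaled by TMM factors. Differences between comparisons were tested as interactions in joint fits, and shared calls were set against the product of list sizes with Fisher's exact test, 2-sided. DESeq2 1.42.0, limma voom (limma 3.58.1), other scalings, filters and a replicate block were alternatives, and each library was left out in turn. With 2 libraries per group, leaving out 1 leaves a lone library, which is assumed to vary like the others.

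Overall 37 gene lists were fixed beforehand, covering the transcription machinery, stress and metabolic programs, the cell cycle, blood lineages and, for thymocytes, markers of other cell types of the thymus. They were tested with camera on log2 CPM (prior count 2) at a preset correlation of 0.01, adjusted over the lists with at least 5 tested members, with an estimated correlation and fry as alternatives. Mitochondrially encoded messengers and the mouse erythroid markers had fewer tested members and were not tested. A separate family of 6 lists came from the tables' coordinates: the longest and shortest 10% of genes by span, genes with 1 exon, downstream neighbours (5′ end within 5 kb after the 3′ end of a same-strand gene), tail-to-tail genes (3′ ends within 5 kb on opposite strands) and divergent partners (5′ ends within 2 kb on opposite strands), each of the last 3 beside a gene at least 3 log2 CPM higher.

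Genes were named by a rule: the targeted gene, the other members of the PAF1 complex and PPP1R10; per comparison the 6 largest rises and 6 largest falls among called genes with a mean of at least 5 CPM and no overlap between groups; from each called list up to 3 members with the smallest adjusted p in its direction and 1 the other way; and 3 per direction for each interaction and overlap. Symbols of clones, antisense genes and pseudogenes were passed over. Some genes picked by the rule are left unnamed.

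The procedure was run first on simulated counts with 200 changed genes. Of 2-fold changes it recovered 83.3% for the PNUTS set over 13409 genes, 97% for the LEO1 set over 14170, 78.8% for HEL over 12864, 92.4% for CCRF-CEM over 12511 and 33.3% for thymocytes over 11974, and of 1.5-fold changes 16.2%, 82.4%, 57.4%, 70.6% and 1.5% in this order. For the difference between the K562 knockouts it recovered 84.8% of 2-fold changes over 13354 genes, and for that between HEL and CCRF-CEM 77.3% over 11415.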

Results

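PolyA RNA was sequenced in 26 libraries, 20 human and 6 mouse, which fall into 10 groups of 2 or 3 libraries and were deposited as 5 count tables. In the human chronic myeloid leukemia line K562, 3 libraries of PNUTS knockout cells were set beside 3 control libraries, and 3 libraries of LEO1 knockout cells beside 3 other control libraries. In the erythroleukemia line HEL and in the T cell acute lymphoblastic leukemia line CCRF-CEM, 2 libraries of cells with a short hairpin against PAF1 (shPAF1) were set beside 2 with a control hairpin (shCtrl). In mouse CD4+CD8+ double-positive (DP) thymocytes, 3 libraries labelled Paf1 cKO (floxed Paf1 with Lck+ in the genotype label) were set beside 3 labelled Paf1 WT (floxed Paf1 alone). PAF1 and LEO1 are members of the PAF1 complex, which travels with RNA polymerase II, and PNUTS, encoded by PPP1R10, is a nuclear subunit of protein phosphatase 1 that acts at transcription termination. By the title of the series, the question is how this complex bears on transcriptional termination and reinitiation.

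The total count per library ran from 23.1 to 32.6 M in the PNUTS set, 34.9 to 43.9 M in the LEO1 set, 11.6 to 15.6 M in HEL, 13.8 to 15.9 M in CCRF-CEM and 15.9 to 25.4 M in thymocytes (M, 1e6 counts). The totals are fragments in the K562 and thymocyte tables and reads in the HEL and CCRF-CEM tables, per the file names. The labels do not say whether replicates came from separate cultures, clones or animals, so the p-values measure only the spread between these libraries. One library stood apart in its RNA: genes of RNAs without a poly(A) tail took 15.4% of the counts in HEL shCtrl replicate 1 (95% Wilson interval 15.39% to 15.43%, counting error only) and 3.31% to 4.54% in the other HEL libraries. Values below are TMM-scaled counts per 1e6 counts (CPM, mean ± SD) or log2 fold changes of treated over control with an approximate standard error from the F statistic, and fold changes come from the fitted model.

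The targeted gene was compared first. LEO1 (chromosome 15, 51938025 to 51971801, hg38) fell from 53.9 ± 0.731 CPM in 3 control libraries to 4.15 ± 0.244 CPM in 3 LEO1 knockout libraries, 13.0-fold. PAF1 (chromosome 19, 39385630 to 39391195, hg38) fell from 66.3 ± 3.06 to 6.36 ± 0.849 CPM in HEL, 10.4-fold, and from 123 ± 1.74 to 18.2 ± 1.58 CPM in CCRF-CEM, 6.75-fold (n = 2 libraries per group). PPP1R10 (chromosome 6, 30600400 to 30617307, hg38) fell only from 146 ± 16.9 to 114 ± 12.2 CPM in the PNUTS knockout (n = 3 per group), 1.28-fold. RNA levels do not measure the protein, so the PPP1R10 value leaves the loss of PNUTS itself unmeasured. Every knockout or knockdown library lay below every control library of its set for these 3 genes. In thymocytes, Paf1 stood at 101, 98.3 and 37.2 CPM in the libraries labelled WT replicates 1, 2 and 3, and at 60, 68.1 and 27.1 CPM in cKO replicates 1, 2 and 3. The library labelled WT replicate 3 thus held less Paf1 RNA than cKO replicates 1 and 2. Each cKO library lay below the WT library of the same number.

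**Figure D1:**
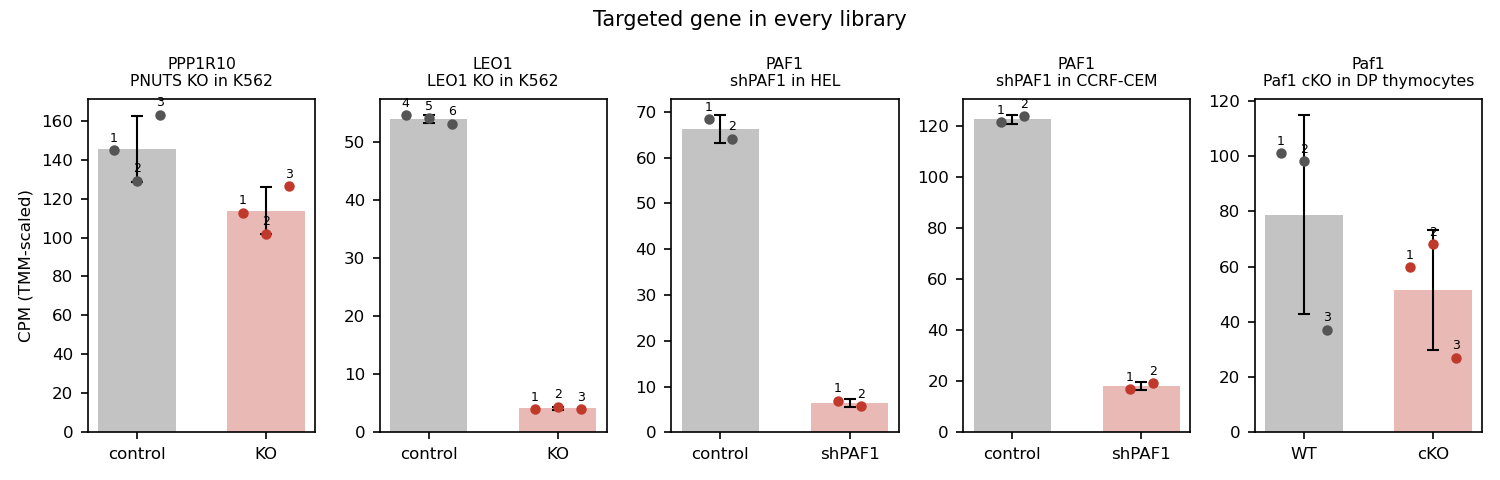
Level of the targeted gene in each library, in TMM-scaled CPM on axes that start at 0. Bars are group means, error bars are SD and each point is a library with its replicate number. LEO1 and PAF1 fell 6.75-fold or more, PPP1R10 fell 1.28-fold, and the library labelled WT replicate 3 lay at 37.2 CPM of Paf1.

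In PNUTS knockout K562 cells, 23 of 35 genes of the red cell lineage rose and 7 of 13 myeloid genes fell. Both lists were called, and both calls were lost with an estimated correlation between genes (adjusted p = 0.143 and 0.296). HBE1, the embryonic beta-like globin, rose 8.12-fold, from 379 ± 30.3 to 3075 ± 179 CPM (n = 3 per group), and SLC4A1, the band 3 anion exchanger of red cells, rose 8.63-fold. ITGAM, the CD11b integrin of myeloid cells, fell 12.5-fold, from 6.03 ± 0.174 to 0.477 ± 0.143 CPM. Over all genes tested, 1949 were higher and 1944 lower of 13553 (edgeR, adjusted p < 0.05), of which 616 and 647 changed at least 2-fold. The replicate numbers may pair these libraries, since same-numbered control and knockout libraries deviated alike from their group means (r = 0.475, 0.475 and 0.698 across genes, which are not independent replicates). Control 1 with knockout 2 and control 2 with knockout 1 also gave r = 0.232 and 0.207, so pairs were not told apart from a replicate 3 that differs. With the replicate as a block 3670 genes were higher and 3203 lower. Named genes, lists, overlaps and differences come from fits without a block unless said otherwise, as do fits that leave out 1 library.

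The genes that rose furthest by the naming rule were MAGEB16, a melanoma antigen family member (log2 fold change 6.96 ± 0.22), TDRD15 (5.86 ± 0.29), RAP1GAP2 (5.06 ± 0.21), ABCB1, the multidrug exporter P-glycoprotein (4.95 ± 0.21), and TUBA3C (4.0 ± 0.18), an alpha-tubulin whose reads can be shared with near-identical copies. MAGEB16 went from 0.150 to 20 CPM and ABCB1 from 1.11 to 34.4 CPM. Those that fell furthest were PCAT14, a long noncoding RNA (−5.58 ± 0.27), INPP5D, the SHIP1 phosphatase of blood cells (−5.05 ± 0.25), CD24, a surface glycoprotein (−4.76 ± 0.17), GYG2, a glycogenin (−4.66 ± 0.26), DLK1, a NOTCH ligand-like membrane protein (−4.61 ± 0.20), and LAMB1, a laminin chain (−4.51 ± 0.26). DLK1 went from 389 to 15.9 CPM and CD24 from 114 to 4.19 CPM. These genes had an edgeR adjusted p of 1.36e-05 or less, and none overlapped between the groups, a condition of the naming rule.

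Among lists fixed before the data were examined, 23 of 35 erythroid genes rose, 3 fell and 9 did not pass (24 and 3 adjusted over the list alone). HBE1 rose by 3.02 ± 0.08 and SLC4A1 by 3.11 ± 0.09 in log2, while TMCC2 fell by 1.87 ± 0.31. The list's camera adjusted p was 1.15e-07, and its adjusted p = 0.143 with an estimated correlation. Of 13 myeloid and monocyte genes, 7 fell, none rose and 6 did not pass (7 and 0 adjusted over the list alone). Beside ITGAM, examples were CD33 (−2.06 ± 0.16) and LYZ, lysozyme, at −1.58 ± 0.15 (adjusted p = 0.000136; adjusted p = 0.296 with an estimated correlation). Of 9 T cell genes, a lineage K562 cells do not belong to, 6 rose, 2 fell and 1 did not pass (6 and 2 adjusted over the list alone). Their median log2 fold change was 0.676, against 0.718 for erythroid genes. The list did not pass camera (adjusted p = 0.0544, and 0.624 with an estimated correlation) but passed fry (adjusted p = 0.0178).

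Of 17 genes of the unfolded protein response, 9 fell and 8 did not pass (11 lower adjusted over the list alone), among them the endoplasmic reticulum chaperones and quality control factors PDIA4 (−0.61 ± 0.08), EDEM1 (−0.61 ± 0.09) and DNAJB11 (−0.80 ± 0.12). Of 20 genes of cholesterol synthesis and SREBP2 targets, 8 fell and 12 did not pass (9 lower adjusted over the list alone). Examples were NSDHL (−1.08 ± 0.09) and FDPS (−0.36 ± 0.08). Of 26 genes of the integrated stress and amino acid response, 12 fell, 3 rose and 11 did not pass (13 and 3 adjusted over the list alone). Here the serine synthesis enzyme PSAT1 (−0.80 ± 0.07), STC2 (−1.13 ± 0.13) and GPT2 (−0.95 ± 0.12) were lower and PSPH, also of serine synthesis, higher (0.52 ± 0.10). Camera adjusted p-values were 0.000794, 0.00171 and 0.0165, and adjusted p = 0.266, 0.624 and 0.624 with an estimated correlation.

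In 5 further lists called higher in the PNUTS knockout, most members did not pass. Of 82 cytosolic ribosomal protein genes, 27 rose, 4 fell and 51 did not pass (30 and 5 adjusted over the list alone). In this list RPS20 (0.43 ± 0.06) and RPS12 (0.50 ± 0.10) were higher and RPS4X lower (−0.49 ± 0.07). Of 15 small nucleolar RNA host genes, 5 rose and 10 did not pass (6 higher adjusted over the list alone). Examples were DANCR (0.96 ± 0.08), SNHG7 (0.55 ± 0.09) and ZFAS1 (0.43 ± 0.08), of which SNHG7 and ZFAS1 overlap other genes. Of 41 replication-dependent histone genes, 14 rose, 1 fell and 26 did not pass (15 and 2 adjusted over the list alone). Among these HIST1H2BG (0.80 ± 0.10), HIST1H2AE (1.12 ± 0.16) and HIST1H3H (0.63 ± 0.10) were higher and HIST2H2BE lower (−0.82 ± 0.11). Genes of other RNAs without a poly(A) tail took 0.648%, 1.48% and 1.39% of the counts in knockout replicates 1, 2 and 3. Their share was 0.584%, 0.959% and 0.417% in control replicates 1, 2 and 3, and whether this bears on the histone rise was not tested. Of 20 immediate early genes, 8 rose, 1 fell and 11 did not pass (8 and 1 adjusted over the list alone). Of them, EGR1 (1.07 ± 0.08), BTG2 (1.44 ± 0.12) and DUSP1 (0.75 ± 0.12) were higher and IER3 lower (−0.97 ± 0.18). Of 14 heat shock genes, 4 rose and 10 did not pass (5 higher adjusted over the list alone). Examples were HSPA8 (0.50 ± 0.06), HSP90AB1 (0.33 ± 0.06) and DNAJA1 (0.33 ± 0.08). Camera adjusted p-values in this order were 0.00232, 0.00183, 0.00949, 0.0116 and 0.0353, and adjusted p = 0.624 with an estimated correlation for each but the host genes, at adjusted p = 0.296. The heat shock call was also lost without control replicate 2 (0.0640) or 3 (0.117), or knockout replicate 1 (0.0931) or 2 (0.0749).

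Within the PAF1 complex, CDC73 (−0.46 ± 0.11) and RTF1 (−0.33 ± 0.09) fell and CTR9 rose (0.36 ± 0.11), with edgeR adjusted p of 0.0144, 0.0262 and 0.0399, while WDR61 (0.11 ± 0.07), LEO1 (−0.13 ± 0.10) and PAF1 (−0.04 ± 0.16) did not pass. Divergent partners, genes whose 5′ end lies within 2 kb of that of a more highly expressed gene on the opposite strand, rose: 140 were higher, 29 lower and 461 did not pass of 630 (137 and 28 adjusted over the list alone). Their median log2 fold change was 0.29. Camera gave adjusted p = 0.000881, and adjusted p = 0.0851 with an estimated correlation. The 5 other lists built from gene structure (longest 10% and shortest 10% by span, genes with 1 exon, downstream neighbours and tail-to-tail genes) had adjusted p from 0.110 to 0.751, and the 18 other gene lists from 0.0544 to 0.779. With the replicate as a block, ribosome biogenesis and MYC targets, 1 of these 18, was called higher (adjusted p = 0.0231), and lost with an estimated correlation (adjusted p = 0.627). The same list was called without control replicate 1 (0.0148) or knockout replicate 3 (0.0408). Those 18 were the PAF1 complex, cleavage and termination factors, elongation factors, Integrator subunits, oxidative phosphorylation, ribosome biogenesis and MYC targets, p53 targets, BCL2 family, interferon-stimulated genes, NF-kappaB targets, both cell cycle lists, autophagy and lysosome, DNA repair, MLL-linked HOX genes, megakaryocyte genes, T cell genes and NOTCH targets. Median, mean and test differed in sign for p53 targets, the BCL2 family, tail-to-tail genes and the longest 10%. The PPP1R10 call (adjusted p = 0.0453) was lost when control replicate 1 or 3, or knockout replicate 1 or 2, was left out (adjusted p from 0.0992 to 0.147), and without control replicate 2 only 1252 genes were higher. RTF1, CTR9, DNAJA1 and the histone, heat shock and integrated stress lists each lost their call with at least 1 library left out.

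In LEO1 knockout K562 cells, 24 of 35 erythroid, 19 of 26 interferon-stimulated and 29 of 42 histone genes rose, while 19 of 25 amino acid response, 16 of 25 DNA repair and 22 of 37 replication genes fell. All 6 list calls were lost with an estimated correlation (adjusted p from 0.309 to 0.408). ALAS2, the first enzyme of heme synthesis in red cells, rose 6.46-fold (n = 3 per group), and CA1, a red cell carbonic anhydrase, rose 42.3-fold. OAS3, an interferon-induced sensor enzyme of double-stranded RNA, rose 7.20-fold. PPP1R10 fell 2.54-fold, from 137 ± 4.83 to 53.9 ± 1.46 CPM, further than in the PNUTS knockout itself. Over all genes tested, 4873 were higher and 4896 lower of 14340 (edgeR, adjusted p < 0.05), and of the genes that changed at least 2-fold, 1929 were higher and 741 lower.

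The genes that rose furthest were CA3, a muscle carbonic anhydrase (log2 fold change 7.93 ± 0.19), CAPN6 (7.68 ± 0.17), TCN1, a vitamin B12-binding protein (7.60 ± 0.10), AMBN, an enamel matrix protein (6.99 ± 0.16), IGFL2 (6.98 ± 0.17) and COL3A1, a fibrillar collagen (6.89 ± 0.18). TCN1 went from 0.721 to 141 CPM, and CA3, which overlaps an antisense gene, from 0.0730 to 19.1 CPM. Those that fell furthest were FGF13 (−6.91 ± 0.30), IGF1, insulin-like growth factor 1 (−6.49 ± 0.20), LONRF3 (−6.38 ± 0.18), H19, an imprinted noncoding RNA (−6.33 ± 0.28), COLGALT2, a collagen galactosyltransferase (−6.10 ± 0.10), and COL1A2, a collagen chain (−5.42 ± 0.08). COL1A2 went from 89.4 to 2.08 CPM and IGF1 from 45.2 to 0.490 CPM. All 12 had an edgeR adjusted p of 1.31e-05 or less with no overlap between the groups.

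Of 35 erythroid genes, 24 rose, 5 fell and 6 did not pass (24 and 5 adjusted over the list alone). SLC4A1 (3.30 ± 0.05), ALAS2 (2.69 ± 0.04) and CA1 (5.40 ± 0.09) were higher, and TFRC, the transferrin receptor, was lower (−0.47 ± 0.04). Of 26 interferon-stimulated genes, 19 rose, 3 fell and 4 did not pass (19 and 3 adjusted over the list alone). Here OAS3 (2.85 ± 0.09), RSAD2, an antiviral enzyme (2.40 ± 0.10), and GBP2, a guanylate-binding protein (4.31 ± 0.21), were higher and IFITM1 lower (−1.41 ± 0.04). Of 42 histone genes, 29 rose, none fell and 13 did not pass (29 higher adjusted over the list alone). Examples were HIST1H2AI (1.80 ± 0.07), HIST1H3H (1.53 ± 0.06) and the linker histone HIST1H1C (0.76 ± 0.04). Of 22 autophagy and lysosome genes, 15 rose, 4 fell and 3 did not pass (16 and 4 adjusted over the list alone). In this list the proteases CTSB (1.01 ± 0.04) and CTSL (1.05 ± 0.05) and the sialidase NEU1 (0.66 ± 0.04) were higher and LAMP2 lower (−0.75 ± 0.05). Of 82 ribosomal protein genes, 50 rose, 9 fell and 23 did not pass (50 and 9 adjusted over the list alone). Among these RPS3A (0.61 ± 0.04), RPL34 (0.54 ± 0.04) and RPS12 (0.50 ± 0.04) were higher and RPL39 lower (−0.81 ± 0.04). Camera adjusted p-values in this order were 0.000114, 0.000979, 0.000145, 0.0112 and 0.00698, and adjusted p = 0.309, 0.309, 0.408, 0.322 and 0.438 with an estimated correlation.

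Of 25 genes of the integrated stress and amino acid response, 19 fell, 2 rose and 4 did not pass (19 and 2 adjusted over the list alone). Of them, DDIT4 (−1.38 ± 0.05), STC2 (−2.02 ± 0.09) and PHGDH, the first enzyme of serine synthesis (−1.08 ± 0.06), were lower and PPP1R15A higher (0.73 ± 0.05). Of 31 genes of ribosome biogenesis and MYC targets, 24 fell, 3 rose and 4 did not pass (24 and 3 adjusted over the list alone). Here CAD of pyrimidine synthesis (−0.51 ± 0.04) and ODC1 of polyamine synthesis (−0.45 ± 0.04) were lower and NOLC1, a nucleolar protein, higher (0.38 ± 0.04). Of 25 DNA repair genes, 16 fell, 1 rose and 8 did not pass (16 and 1 adjusted over the list alone). In this list the helicase BLM (−1.19 ± 0.05), FANCI (−0.81 ± 0.04) and the kinase ATM (−1.03 ± 0.06) were lower and XRCC2 higher (0.56 ± 0.05). Of 37 genes of G1/S and DNA replication, 22 fell, 6 rose and 9 did not pass (24 and 6 adjusted over the list alone). Among these GINS1 (−0.61 ± 0.05), CDC45 (−0.41 ± 0.04) and UHRF1 (−0.40 ± 0.04) were lower and TK1 higher (0.29 ± 0.04). Of 17 genes of the unfolded protein response, 12 fell and 5 did not pass (13 lower and 1 higher adjusted over the list alone). Examples were XBP1 (−0.56 ± 0.05) and PDIA6 (−0.42 ± 0.04). Of 20 genes of cholesterol synthesis, 12 fell, 2 rose and 6 did not pass (12 and 2 adjusted over the list alone). LSS, which closes the sterol rings, was lower (−0.72 ± 0.05). Camera adjusted p-values in this order were 0.000371, 0.000979, 0.00414, 0.0164, 0.00698 and 0.0164, and adjusted p = 0.309 for the first and 0.408 for the others with an estimated correlation.

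Among other members of the complex, WDR61 fell (−0.72 ± 0.05) and CTR9 rose (0.53 ± 0.04), with edgeR adjusted p of 1.19e-10 and 9.2e-10. RTF1 (−0.11 ± 0.04) and CDC73 (−0.13 ± 0.05) fell slightly, and PAF1 did not pass (0.06 ± 0.05). Tail-to-tail genes, whose 3′ end lies within 5 kb of that of a more highly expressed gene on the opposite strand, were called as a list: 284 rose, 123 fell and 276 did not pass of 683 (279 and 123 adjusted over the list alone). Their median log2 fold change was 0.26. Camera gave adjusted p = 0.0366, and adjusted p = 0.541 with an estimated correlation, and genes matched on expression had a median of 0.25. The other 5 structure lists had adjusted p from 0.0790 to 0.854 and the 17 other gene lists from 0.0575 to 0.929, the lowest being cleavage and termination factors, of which 14 fell and 4 rose of 33. Those 17 also held the PAF1 complex, elongation factors, Integrator subunits, oxidative phosphorylation, small nucleolar RNA host genes, p53 targets, BCL2 family, heat shock, immediate early, NF-kappaB, G2/M, MLL-linked HOX, megakaryocyte, myeloid, T cell and NOTCH lists. Signs of median, mean and test differed for elongation factors, oxidative phosphorylation, p53 targets, MLL-linked HOX genes, NOTCH targets, the longest 10% and downstream neighbours. No paired analysis was possible because the controls are numbered 4 to 6 and the knockouts 1 to 3. The tail-to-tail call was lost without control replicate 4 (adjusted p = 0.0576), knockout replicate 2 (0.105) or knockout replicate 3 (0.0511) and with library totals as scaling (0.0662), and RTF1 and CDC73 lost theirs with some libraries left out.

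Calls in the 2 K562 knockouts were shared more often than expected in each same direction and in 1 of the 2 opposite directions. Among 13354 genes tested in both, 864 rose in both against 590 expected and 797 fell in both against 693 expected (Fisher's exact test, 2-sided, p = 3.69e-46 and 1.16e-07, which describe the overlap of the lists, since genes are not independent). SLC4A1, EPHB6, a kinase-dead ephrin receptor, and AQP1, the water channel of red cells, led the shared rise: EPHB6 rose by 3.21 ± 0.11 in the PNUTS and 1.28 ± 0.05 in the LEO1 knockout, and AQP1 by 2.22 ± 0.09 and 2.46 ± 0.06. Among shared falls, COL1A2 changed by −2.32 ± 0.08 in the PNUTS and −5.42 ± 0.08 in the LEO1 knockout. SCG3, a secretory granule protein, changed by −2.50 ± 0.09 and −1.76 ± 0.05, and IFITM1 by −2.07 ± 0.08 and −1.41 ± 0.04. Opposite calls were made for 1252 genes: 710 fell in the PNUTS and rose in the LEO1 knockout, against 597 expected, and 542 went the other way, against 685 expected (Fisher's exact test, 2-sided, p = 3.09e-09 and 7.36e-14, over the same genes). The first count was 1.19 times its expected value, and the shared fall 1.15 times. Over all these genes the log2 fold changes had r = 0.0705 and rho = 0.0912, across genes that are not independent.

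The difference between the K562 knockouts was tested in a joint fit of 12 libraries. The effect was larger (more positive) in the LEO1 knockout for 3302 genes and in the PNUTS knockout for 3601 of 14727 (edgeR, adjusted p < 0.05). FN1, fibronectin, rose by 0.81 in the LEO1 and fell by 4.30 in the PNUTS knockout, a difference of 5.09 ± 0.11. ENC1, an actin-binding protein, rose by 4.05 and fell by 1.91 (difference 5.93 ± 0.14), and TCN1 rose by 7.60 and 1.38 (6.19 ± 0.16). In the other direction stood COLGALT2 (−6.10 in LEO1 and 0.33 in PNUTS), DCAF4L2 (−5.36 and 1.33) and HBE1 (−0.20 and 3.02), so the embryonic globin rose in the PNUTS knockout and fell in the LEO1 knockout. Each set has its own controls, so a difference between the sets of cultures is part of this contrast.

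**Figure D2:**
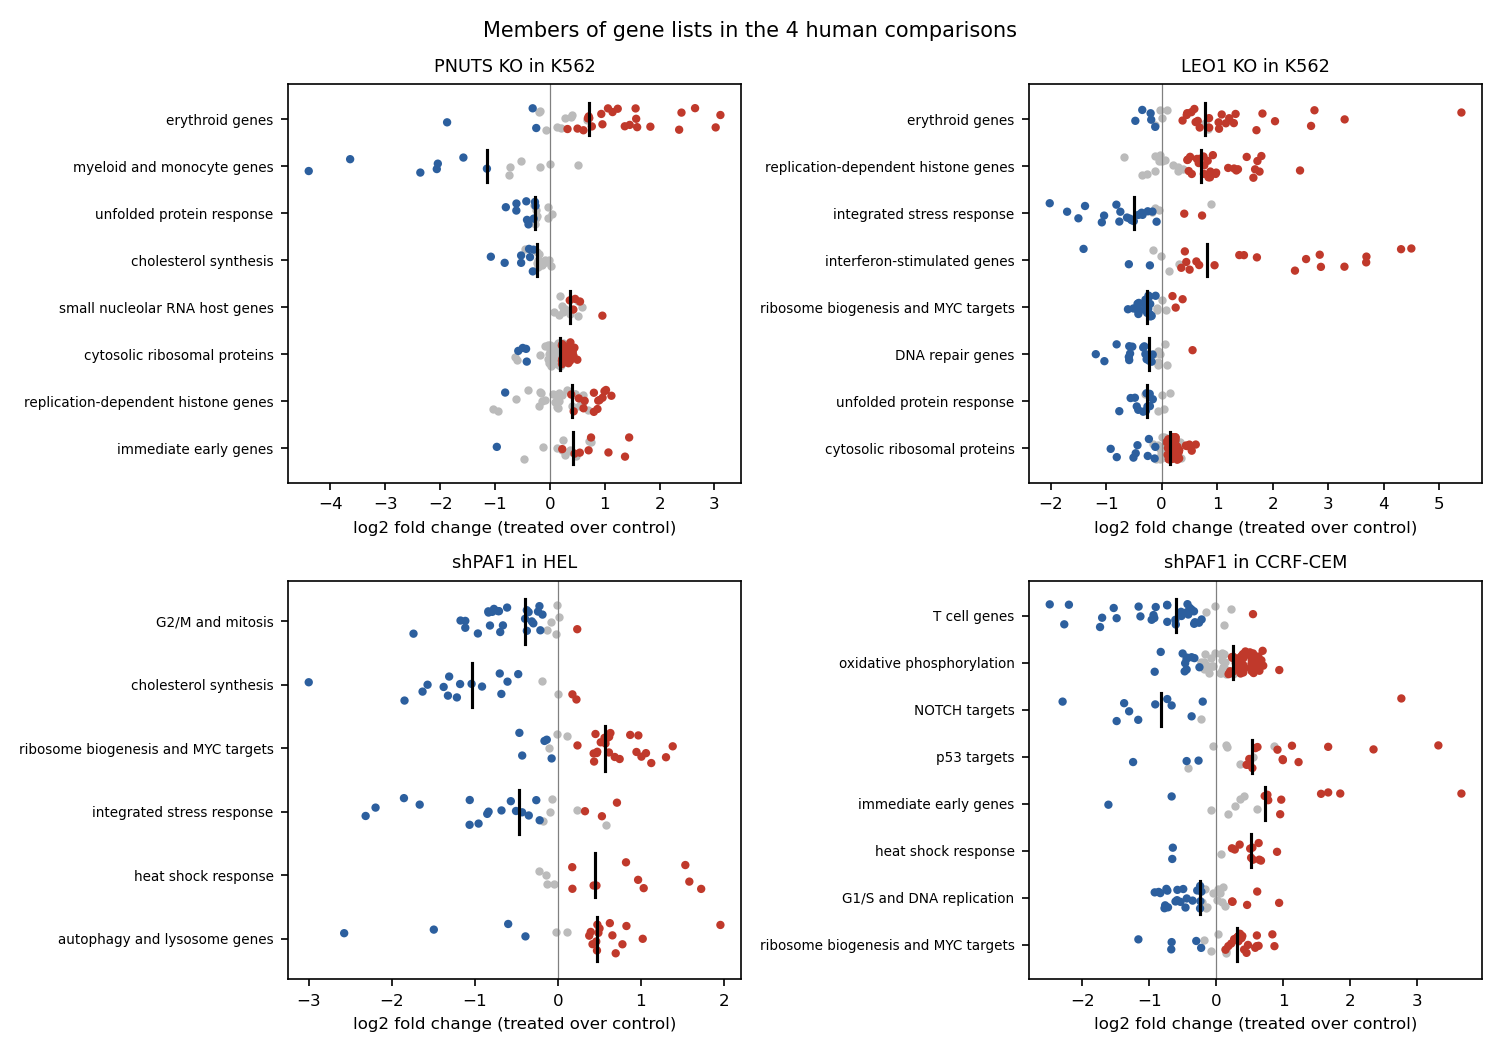
Log2 fold change of each tested member of up to 8 called gene lists in the 4 human comparisons, treated over control. Red and blue points passed the edgeR test upward and downward, grey points did not, and black bars are list medians, such as 0.72 for erythroid genes in the PNUTS knockout and −0.60 for T cell genes in CCRF-CEM.

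In HEL cells with PAF1 knocked down, 25 of 31 mitotic and 15 of 19 cholesterol synthesis genes fell, and 23 of 31 ribosome biogenesis, 10 of 14 heat shock and 15 of 21 lysosome genes rose. All 5 list calls were lost with an estimated correlation (adjusted p from 0.584 to 0.589), and the lysosome call also with library totals as scaling (0.0545). In simulated counts, a list of 30 genes all raised 2-fold had camera adjusted p = 0.00696 in HEL and 0.0110 in CCRF-CEM with an estimated correlation. It was adjusted there beside an unchanged list alone. Adjustment over 28 lists is heavier, so a lost call in these lines does not show that a list was unchanged. BUB1, a spindle checkpoint kinase, fell 2.16-fold, from 976 ± 5.39 to 451 ± 6.75 CPM (n = 2 per group), and HMGCS1, an early enzyme of cholesterol synthesis, fell 3.60-fold, from 255 ± 1.19 to 70.9 ± 6.78 CPM. NOLC1 rose 2.47-fold and HSPA8, the constitutive HSP70, 1.96-fold. Over all genes tested, 4045 were higher and 3937 lower of 13082 (edgeR, adjusted p < 0.05), of which 725 and 982 changed at least 2-fold.

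The genes that rose furthest were NBPF6 (log2 fold change 3.42 ± 0.30) and NBPF4 (3.41 ± 0.27), members of a near-identical family whose reads can be shared, the noncoding RNA LINC01963 (3.41 ± 0.18), ENC1, which overlaps another gene (3.15 ± 0.10), C2orf66 (2.98 ± 0.20) and PLEKHA7, a junction protein (2.95 ± 0.13). ENC1 went from 8.34 to 73.3 CPM. Those that fell furthest, beside PAF1 (−3.38 ± 0.11), were WNT5A, a secreted WNT ligand (−3.49 ± 0.30), STARD4, a sterol carrier (−3.0 ± 0.10), CITED1 (−2.79 ± 0.21) and EPS8L1 (−2.74 ± 0.22). STARD4 went from 80.6 to 10.1 CPM. These genes had an edgeR adjusted p of 5.35e-10 or less with no overlap between the groups.

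Of 31 G2/M and mitosis genes, 25 fell, 1 rose and 5 did not pass (25 and 1 adjusted over the list alone). Here HMMR (−1.74 ± 0.07), CDK1, the mitotic kinase (−1.17 ± 0.06), and BUB1 (−1.11 ± 0.04) were lower, while ECT2 was higher (0.23 ± 0.09). Of 19 genes of cholesterol synthesis, 15 fell, 2 rose and 2 did not pass (15 and 2 adjusted over the list alone). HMGCS1 (−1.85 ± 0.06), FDFT1 (−1.18 ± 0.05) and SQLE (−1.04 ± 0.05) were lower. Of 24 genes of the integrated stress and amino acid response, 16 fell, 3 rose and 5 did not pass (16 and 3 adjusted over the list alone). In this list PHGDH (−1.85 ± 0.10), the cystine carrier SLC7A11 (−2.32 ± 0.15) and PSAT1 (−1.66 ± 0.11) were lower and SHMT2 higher (0.53 ± 0.06). Of 31 genes of ribosome biogenesis and MYC targets, 23 rose, 5 fell and 3 did not pass (24 and 5 adjusted over the list alone). Among these NOLC1 (1.30 ± 0.05), NOP58 (1.13 ± 0.05) and NOP56 (1.01 ± 0.05) were higher and ENO1, a glycolytic enzyme, lower (−0.46 ± 0.03). Of 14 heat shock genes, 10 rose and 4 did not pass (10 higher adjusted over the list alone). Examples were HSPA8 (0.97 ± 0.03), HSPA1B (1.59 ± 0.05) and HSPA1A (1.54 ± 0.06), of which HSPA1A and HSPA1B are near-identical. Of 21 autophagy and lysosome genes, 15 rose, 4 fell and 2 did not pass (15 and 4 adjusted over the list alone). Of them, LAMP2 (0.70 ± 0.06), ATG2A (1.02 ± 0.11) and CTSB (0.49 ± 0.05) were higher and WIPI1 lower (−1.49 ± 0.09). Camera adjusted p-values in this order were 1.44e-05, 7.62e-05, 0.0167, 0.000174, 0.0167 and 0.0282, and adjusted p = 0.584 with an estimated correlation for each but heat shock, at adjusted p = 0.589.

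Other members of the complex moved less than PAF1: RTF1 (0.67 ± 0.05), WDR61 (0.62 ± 0.12) and CTR9 (0.15 ± 0.05) rose, PPP1R10 fell (−0.14 ± 0.04), and CDC73 (−0.13 ± 0.06) and LEO1 (−0.07 ± 0.06) did not pass. The 22 other gene lists had camera adjusted p from 0.0502 to 0.941, the lowest being elongation factors, of which 16 rose and 4 fell of 30. The others were the PAF1 complex, cleavage and termination factors, Integrator subunits, histones, ribosomal proteins, oxidative phosphorylation, small nucleolar RNA host genes, p53 targets, BCL2 family, unfolded protein response, immediate early, interferon-stimulated, NF-kappaB, G1/S, DNA repair, MLL-linked HOX, erythroid, megakaryocyte, myeloid, T cell and NOTCH lists. None of the 6 structure lists passed (adjusted p from 0.650 to 0.978). The PAF1 complex, ribosomal protein, immediate early and T cell lists had a median, mean and test of differing sign. Histone genes had a median of −1.95 over 18 genes, 3 of which fell, and the list passed only in some settings, such as without shCtrl replicate 2 (adjusted p = 1.40e-19), which leaves the shCtrl library rich in RNA without a poly(A) tail as the lone control. With library totals as scaling, PPP1R10 (adjusted p = 0.517), CTR9 (0.205), ECT2 (0.120) and the autophagy list (0.0545) lost their calls, and CTR9 and ECT2 also lost theirs with some libraries left out.

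In CCRF-CEM cells with PAF1 knocked down, 30 of 35 T cell and 10 of 12 NOTCH genes fell, and 14 of 24 p53 targets, 9 of 17 immediate early and 47 of 81 oxidative phosphorylation genes rose. All 5 list calls were lost with an estimated correlation (adjusted p from 0.435 to 0.530), which, as in HEL, does not show that a list was unchanged. TCF7, a transcription factor of early T cells, fell 2.8-fold, from 1490 ± 19.9 to 533 ± 38.4 CPM (n = 2 per group), and NOTCH1, the receptor that drives many T cell leukemias, fell 2.24-fold. CDKN1A, the p53-induced inhibitor of cyclin-dependent kinases, rose 9.95-fold, from 1.13 ± 0.0756 to 11.3 ± 1.77 CPM. Over all genes tested, 3441 were higher and 3554 lower of 12694 (edgeR, adjusted p < 0.05), of which 521 and 706 changed at least 2-fold.

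The genes that rose furthest were GBP2 (log2 fold change 5.29 ± 0.28) and IFIT3 (4.47 ± 0.27), both induced by interferon, FAM30A, a noncoding RNA (4.20 ± 0.95), PLAU, urokinase (3.91 ± 0.32), TNXB (3.76 ± 0.22), which overlaps 4 genes including its copy TNXA, and CDKN1A (3.32 ± 0.24), which overlaps DINOL. GBP2 went from 0.439 to 17.5 CPM. Those that fell furthest were CDHR1 (−4.90 ± 0.26), TSPAN11 (−4.64 ± 0.27), SERINC2 (−3.72 ± 0.28), IGLL1, a surrogate light chain (−3.65 ± 0.22), PPFIA4 (−3.42 ± 0.23) and ADGRB2 (−2.93 ± 0.23). CDHR1 went from 16.3 to 0.537 CPM. FAM30A had an edgeR adjusted p of 0.0253 and lost its call without either shCtrl library (0.0757 and 0.0526), with voom (0.153) or with no filter (0.166), while the others had 4.13e-07 or less.

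Of 35 T cell genes, 30 fell, 1 rose and 4 did not pass (31 and 1 adjusted over the list alone). Here CD1A (−2.27 ± 0.09) and CD1E (−1.53 ± 0.06), lipid antigen presenters of immature thymocytes, and TCF7 (−1.49 ± 0.06) were lower and CD3G of the T cell receptor complex higher (0.55 ± 0.06). Of 12 NOTCH targets, 10 fell, 1 rose and 1 did not pass (10 and 1 adjusted over the list alone). In this list NOTCH3 (−2.29 ± 0.12), NOTCH1 (−1.16 ± 0.07) and MYC (−0.67 ± 0.07) were lower and NRARP higher (2.76 ± 0.68, from 0.221 to 1.56 CPM). Of 37 genes of G1/S and DNA replication, 21 fell, 5 rose and 11 did not pass (21 and 5 adjusted over the list alone). Among these the helicase subunits MCM6 (−0.76 ± 0.06) and MCM2 (−0.86 ± 0.07) and CHAF1B (−0.92 ± 0.08) were lower and CCNE1, cyclin E1, higher (0.94 ± 0.13). Of 24 p53 targets, 14 rose, 3 fell and 7 did not pass (15 and 4 adjusted over the list alone). Of them, BTG2 (1.67 ± 0.09), TIGAR (1.13 ± 0.10) and the apoptosis inducer PMAIP1 (0.99 ± 0.09) were higher and DDB2 lower (−1.24 ± 0.09). Camera adjusted p-values in this order were 1.52e-07, 0.00162, 0.0117 and 0.00162, and adjusted p = 0.435 for each with an estimated correlation.

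Of 81 nuclear genes of oxidative phosphorylation, 47 rose, 11 fell and 23 did not pass (47 and 11 adjusted over the list alone). Here NDUFA4 (0.94 ± 0.07), UQCRC2 (0.65 ± 0.06) and ATP5F1B (0.53 ± 0.06) were higher and ATP5MC2 lower (−0.83 ± 0.07). Of 17 immediate early genes, 9 rose, 2 fell and 6 did not pass (9 and 2 adjusted over the list alone). In this list SGK1 (3.66 ± 0.28), ATF3 (1.56 ± 0.13) and JUN (0.95 ± 0.10) were higher and NR4A3 lower (−1.61 ± 0.51). Of 14 heat shock genes, 11 rose, 2 fell and 1 did not pass (11 and 2 adjusted over the list alone). Among these DNAJA1 (0.91 ± 0.06), HSPA1B (0.67 ± 0.07) and HSP90AB1 (0.54 ± 0.06) were higher and HSPB1 lower (−0.66 ± 0.12). Of 31 genes of ribosome biogenesis and MYC targets, 20 rose, 5 fell and 6 did not pass (21 and 5 adjusted over the list alone). Of them, NOP56 (0.84 ± 0.05), ODC1 (0.87 ± 0.06) and NOLC1 (0.60 ± 0.05) were higher and ENO1 lower (−1.16 ± 0.06). Camera adjusted p-values in this order were 0.00162, 0.00457, 0.00845 and 0.0132, and adjusted p = 0.530, 0.467, 0.435 and 0.435 with an estimated correlation.

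PPP1R10 fell in CCRF-CEM (−0.69 ± 0.05), and CTR9 (0.70 ± 0.06), WDR61 (0.55 ± 0.09), CDC73 (0.49 ± 0.08), LEO1 (0.43 ± 0.07) and RTF1 (0.24 ± 0.06) rose, so every other member of the complex was higher where PAF1 was lower. The 20 other gene lists had camera adjusted p from 0.101 to 0.848, the lowest being interferon-stimulated genes, of which 15 rose and 6 fell of 33, and none of the 6 structure lists passed (0.175 to 0.650). The others were the PAF1 complex, cleavage and termination factors, elongation factors, Integrator subunits, histones, ribosomal proteins, small nucleolar RNA host genes, BCL2 family, integrated stress response, unfolded protein response, NF-kappaB, cholesterol, G2/M, autophagy, DNA repair, MLL-linked HOX, erythroid, megakaryocyte and myeloid lists. For the PAF1 complex, ribosomal proteins, the integrated stress response and downstream neighbours, median, mean and test differed in sign. Without shCtrl replicate 1, only 2362 genes were lower. RTF1 lost its call without either shCtrl library, NRARP without shPAF1 replicate 2, and NR4A3 with DESeq2 or with some libraries left out.

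PAF1 knockdown moved many of the same genes in HEL and CCRF-CEM. Among 11416 genes tested in both, 1565 rose in both against 1076 expected and 1324 fell in both against 935 expected (Fisher's exact test, 2-sided, p = 1.45e-99 and 1.26e-68, over genes that are not independent). H1F0, the replication-independent linker histone, rose by 1.20 ± 0.03 in HEL and 2.58 ± 0.06 in CCRF-CEM, and DYNLL2, a dynein light chain, by 1.12 ± 0.07 and 1.66 ± 0.06. EXOC4, an exocyst subunit, fell by 0.80 ± 0.07 and 1.87 ± 0.09, and IDH2, mitochondrial isocitrate dehydrogenase, by 1.61 ± 0.06 and 1.20 ± 0.06. With the LEO1 knockout added, 510 genes rose in all 3 and 630 fell in all 3 of 10829, a description with no test that includes the overlap of HEL and CCRF-CEM. Genes that rose in both the LEO1 knockout and CCRF-CEM numbered 1023 against 1006 expected, and those that fell in both 1360 against 1166 (Fisher's exact test, 2-sided, p = 0.460 and 8.9e-17). For the LEO1 knockout and HEL, 1334 rose in both against 1215 expected and 1644 fell in both against 1321 expected (Fisher's exact test, 2-sided, p = 5.69e-07 and 2.29e-40). POLR2A, the largest subunit of RNA polymerase II, rose in all 3, by 0.49 ± 0.04 in the LEO1 knockout, 0.46 ± 0.04 in HEL and 0.89 ± 0.06 in CCRF-CEM, as did ZNFX1 (0.65 ± 0.05, 1.27 ± 0.07 and 1.02 ± 0.07) and ZFP36L1 (0.93 ± 0.06, 0.55 ± 0.06 and 1.99 ± 0.09). EXOC4, IDH2 and FADS2, a fatty acid desaturase, fell in all 3, FADS2 by 0.64 ± 0.05, 0.99 ± 0.05 and 1.41 ± 0.09.

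**Figure D3:**
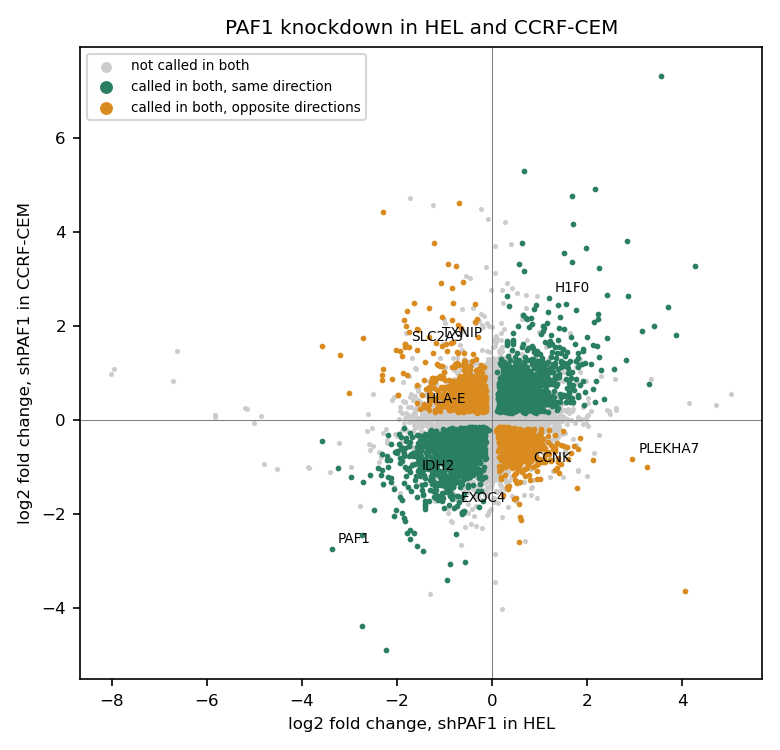
Log2 fold change of each gene tested in both lines, HEL on the horizontal and CCRF-CEM on the vertical axis, each with 2 shPAF1 and 2 shCtrl libraries. Green points were called in the same direction in both lines (1565 upward and 1324 downward). Orange points were called in opposite directions (696 higher in HEL and lower in CCRF-CEM, 732 the other way), and grey points were not called in both.

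The 2 lines also differed. In a joint fit of 8 libraries, the log2 fold change with shPAF1 was larger (more positive, not larger in size) in HEL for 3110 genes and in CCRF-CEM for 2816 of 14427 (edgeR, adjusted p < 0.05). SLC2A3, a glucose transporter, fell by 1.83 in HEL and rose by 1.55 in CCRF-CEM, and TXNIP, a glucose-responsive inhibitor of glucose uptake, fell by 1.18 and rose by 1.63. HLA-E, a nonclassical class I molecule, fell by 1.52 and rose by 0.23. PLEKHA7 rose by 2.95 in HEL and fell by 0.84 in CCRF-CEM, CCNK, the cyclin of CDK12, rose by 0.74 and fell by 1.03, and TSPAN7 rose by 0.98 and fell by 0.93.

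In DP thymocytes, no gene passed between the libraries labelled Paf1 WT and Paf1 cKO. Paf1 itself was 1.53-fold lower in cKO, at 51.7 ± 21.7 CPM against 78.9 ± 36.1 CPM (n = 3 per group), a difference within the spread between libraries. Of 12147 genes, 0 were higher and 0 lower (edgeR, adjusted p < 0.05). At an unadjusted p under 0.05, 53 were higher and 56 lower, fewer than chance alone would give at that threshold. With the replicate as a block, 0 and 0 were called, and 372 were higher and 239 lower at an unadjusted p under 0.05. DESeq2 called 0 and 1, and voom 0 and 0. The 1 gene that DESeq2 called, Erdr1 (−1.37 ± 0.23), is named here after its value was seen. The other members of the complex, Cdc73 (−0.20 ± 0.15), Wdr61 (0.12 ± 0.18), Rtf1 (−0.06 ± 0.12), Leo1 (−0.07 ± 0.15) and Ctr9 (0.05 ± 0.14), and Ppp1r10 (0.03 ± 0.15), did not pass.

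The thymocyte libraries differed among themselves more than between the groups. Il2ra, the CD25 marker of double-negative thymocytes, stood at 13.2, 16.7 and 334 CPM in the libraries labelled WT replicates 1, 2 and 3 and at 137, 19.6 and 269 CPM in cKO replicates 1, 2 and 3. Notch1 stood at 496, 566 and 1617 CPM and at 1064, 521 and 1639 CPM, and Rag1, the recombinase subunit of DP cells, at 7706, 6377 and 3348 CPM and at 4451, 6755 and 5053 CPM. Cd74, which B cells, macrophages and dendritic cells express, stood at 20.7, 22.8 and 79.5 CPM and at 38.0, 37.9 and 141 CPM. Xist was at 2935 and 3578 CPM in WT replicates 1 and 2 with Y genes near 0, at 6.52 and 5.79 CPM in the library labelled WT replicate 3 and in cKO replicate 1, where Ddx3y was at 141 and 109 CPM, and both Xist and Ddx3y were present in cKO replicates 2 and 3 (2191 and 1708 CPM, and 45.4 and 71.8 CPM). The genes named in this account of single libraries were chosen after their values were seen.

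**Figure D4:**
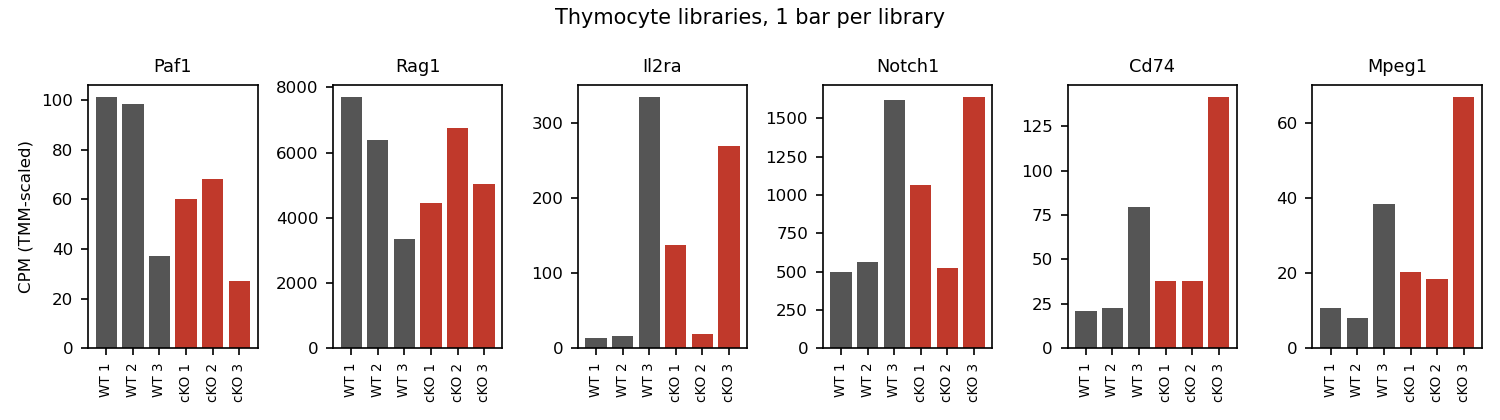
TMM-scaled CPM of 6 genes in each thymocyte library, on axes that start at 0, with the 3 libraries labelled Paf1 WT in grey and the 3 labelled Paf1 cKO in red. The library labelled WT replicate 3 resembled cKO replicate 3 in low Paf1 (37.2 and 27.1 CPM) and high Il2ra (334 and 269 CPM).

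As lists, 14 of 31 were called by camera in thymocytes although 0 of their members passed, alone or adjusted over the list alone. Interferon-stimulated genes (35 genes, median 0.54, adjusted p = 2.86e-13), cytosolic ribosomal proteins (80, 0.17, 5.81e-08), macrophage, dendritic and granulocyte markers (17, 0.91, 1.06e-05), oxidative phosphorylation (78, 0.09, 0.00397) and B cell and plasma cell markers (12, 0.68, 0.00609) lay higher in cKO. G2/M and mitosis (31, −0.23, 9.23e-08), G1/S and DNA replication (37, −0.16, 0.000187), ribosome biogenesis and MYC targets (31, −0.19, 0.000395), MLL-linked HOX genes (8, −0.91, 0.0018), histones (45, −0.24, 0.00609), heat shock (13, −0.30, 0.00609), immediate early (22, −0.42, 0.00703), DNA repair (25, −0.10, 0.0143) and unfolded protein response genes (17, −0.10, 0.0329) lay lower. All were lost with an estimated correlation (adjusted p = 0.639 for oxidative phosphorylation and 0.629 for the others) and with fry. The interferon-stimulated and G2/M lists were still called with each library left out, and each of the other 12 lost its call without at least 1 library. Interferon-stimulated genes moved with macrophage markers: the mean log2 CPM of the first list was 4.92 and of the second 4.20 in cKO replicate 3, and 3.21 and 1.47 in WT replicate 1. The 17 other lists had adjusted p from 0.0555 to 0.958, including double-positive (0.958), double-negative (0.795), post-selection (0.554), natural killer and innate-like (0.95), stromal (0.217) and NOTCH (0.635) lists. The rest were the PAF1 complex, cleavage and termination factors, elongation factors, Integrator subunits, small nucleolar RNA host genes, p53 targets, BCL2 family, integrated stress response, NF-kappaB, cholesterol, and autophagy lists.

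Median, mean and test were of differing sign for the NF-kappaB, NOTCH, double-positive, double-negative and natural killer lists and for the shortest 10%. Genes with 1 exon lay lower in cKO (472 genes, median −0.14, camera adjusted p = 8.43e-06, and adjusted p = 0.437 with an estimated correlation), and the other 5 structure lists had adjusted p from 0.0651 to 0.929. Because the library labelled WT replicate 3 goes against its label in Paf1, each direction here rests on labels that the target gene does not bear out. In simulated data with these libraries' spread, 33.3% of 2-fold and 86.4% of 4-fold changes were recovered over 11974 genes, so most 2-fold differences would be missed with these libraries. No gene called in any human comparison can be set beside a thymocyte call, since the latter number 0.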

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

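The tests of gene lists for a difference between HEL and CCRF-CEM, and the tests of a wrong label, of sex and of macrophage RNA in thymocytes, were chosen only after results were seen. The other tests here were set before their values were seen.

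The effect of shPAF1 differed between HEL and CCRF-CEM in a direct test of the difference, more positive in HEL for 3110 genes and in CCRF-CEM for 2816 (edgeR, adjusted p < 0.05). The HEL minus CCRF-CEM difference in log2 fold change was 3.81 for PLEKHA7, 1.79 for CCNK, 1.93 for TSPAN7, −3.36 for SLC2A3, −2.79 for TXNIP and −1.73 for HLA-E. As lists, ribosome biogenesis and MYC targets (camera adjusted p = 0.0142), G1/S and DNA replication (0.00225) and T cell genes (0.00231) lay higher in HEL relative to CCRF-CEM. The p53 targets (0.00961), integrated stress response (0.00691), interferon-stimulated genes (0.0184), NF-kappaB targets (0.0472), cholesterol synthesis (0.000278) and G2/M and mitosis (2.98e-08) lay lower. With an estimated correlation all 9 were lost, at adjusted p = 0.403 for NF-kappaB targets and 0.113 for the others. No explanation of these differences was tested.

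The first pattern weighed is that no gene was called between the libraries labelled Paf1 WT and Paf1 cKO. All 10 of the 10 splits of the 6 libraries gave at least the real count of 0 genes, which carries no weight because no count can lie below 0, but the split of WT 1, WT 2 and cKO 2 against WT 3, cKO 1 and cKO 3 gave 1115, which points to a structure of the samples that is not the label. A wrong label for the library labelled WT replicate 3 may account for part of the lack of calls. Its log2 ratio of Paf1 to the other members of the complex was −0.815. This lay within the cKO range of −1.09 to 0.307 and below 0.802 and 0.866 in WT replicates 1 and 2. However, this ratio restates the low Paf1 that raised the question and is no separate evidence. Without this library, 4 genes were called higher and 0 lower, and all 4 were Y genes. Leaving it out thus brought back no calls beyond Y genes. In simulated data only 33.3% of 2-fold changes were recovered with all 6 libraries, so this cannot exclude a wrong label. For RNA from macrophages, dendritic cells or granulocytes, that list's mean log2 CPM was higher in WT 3 and cKO 3 than in any other library, by at least 0.958. Mpeg1 stood at 38.3 and 67.0 CPM there against 8.16 to 20.4 in the others. However, abundant Cst3 differed little (41.0 and 45 against 26.4 to 44.0), and a sort for DP cells would remove such cells. This pattern is not specific to these cells. The B cell list (2.43 and 3.16, at most 1.85 elsewhere) and the stromal list (2.09 and 2.25, at most 1.74 elsewhere) showed it too, as did interferon-stimulated genes. The macrophage list also does not follow the split that gave 1115 genes, being nearly equal in cKO 1 and cKO 2 (2.47 and 2.37). Sex of the animals cannot be told apart from the rest: with the level of 4 Y genes as a covariate 0 genes were called. The 2 libraries with Y genes near 0 lay lowest on the first principal component (−36.0 and −37.8). However, cKO 2, with Ddx3y at 45.4 CPM, lay on the same side at −25.8, while WT 3, cKO 1 and cKO 3 lay at 10.9 to 45.7. Presence of Y gene RNA thus did not by itself set the side of this component, though this rests on cKO 2 alone. A biological difference in thymocyte stage stays open and untested. Il2ra and Notch1 were high in WT 3, cKO 1 and cKO 3. The mean log2 CPM of the double-negative list, which holds both genes, was 4.29, 3.61 and 3.81 in these libraries. It was 2.35, 2.53 and 2.31 in WT 1, WT 2 and cKO 2, so it parted the libraries as the split with 1115 genes did.

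The second pattern is that 2-fold changes in the LEO1 knockout were mostly upward, 1929 of 2670 or 72.2%. For scaling set by a few abundant genes, library totals alone gave 73.6% of the 2-fold calls upward, so the share does not rest on the TMM factors. Those factors ran only from 0.988 to 1.013 in this set. The change of scaling could thus hardly have moved the share, and it cannot exclude a role of scaling. Genes near the count floor could account for part: among the 908 such calls with a mean of at least 5 CPM, 60.6% were upward, a value between the bounds set beforehand. Drift between K562 cultures cannot be told apart from a biological effect of losing LEO1: genes with a 2-fold change were more often 2-fold apart between the 2 control sets at equal expression (odds ratio 3.29, 95% interval 2.86 to 3.77), but the 3 LEO1-set controls enter both quantities, so variable genes alone would raise this ratio. In the PNUTS set, where 616 of the 2-fold changes were higher and 647 lower, the ratio was larger still (4.92, 4.23 to 5.73), so a ratio of this size need not go with upward changes. Of the 2-fold calls in the LEO1 knockout, 23.3% were 2-fold apart between the control sets, and 80.9% of these were upward. Among the other calls 69.6% were upward, so the excess was not confined to genes that differed between the control sets.

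The third pattern is the rise of 2 structure lists, divergent partners in the PNUTS and tail-to-tail genes in the LEO1 knockout. For divergent partners the tables argue against low expression, with a median of 0.287 against −0.0351 to 0.0823 for the central 95% of 10000 lists matched on expression, and against shared exons, with 0.305 in the 363 members without exon overlap against −0.0538 to 0.103. For tail-to-tail genes low expression is a candidate explanation, since the median of 0.258 lay within 0.174 to 0.336 of the matched lists, and members without exon overlap (0.258 in 399 genes) lay within 0.133 to 0.346. The count of structure lists was also reached by other splits, in 7 of 10 for the PNUTS set (real 1, highest other 4) and 7 of 10 for the LEO1 set (real 1, highest other 6), and the strand setting of the counting stays open. A biological rise of divergent partners in the PNUTS knockout is therefore no more than a hypothesis.

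Other splits of the same libraries were counted for each result, and 3 libraries against 3 make 10 splits, too few for a share under 0.05. For the PNUTS set, 1 of 10 splits gave as many genes (real 3893, highest other 0) and 1 of 10 as many lists (real 10, highest other 9), and the 3 other splits that part all 3 replicate pairs gave 0 genes and 6 to 8 lists. For the LEO1 set, 1 of 10 gave as many genes (real 9769, highest other 0) and 2 of 10 as many lists (real 11, highest other 11). For thymocytes, 2 of 10 gave as many lists (real 14, highest other 15) and 9 of 10 as many structure lists (real 1, highest other 4). For the difference between the K562 knockouts, 1 of 60 drawn splits, the real one, gave as many genes (real 6903, highest other 4549). These splits relabel control and knockout libraries within each set and take no account of replicate numbers. They ask whether either knockout has an effect, not whether the 2 effects differ, so they cannot exclude chance for the difference. For their shared calls, 1 of 100 drawn pairs of splits gave as many (real 1661, highest other 1252), which says nothing about sharing: the other splits called 0 genes, and the 1252 are the opposite calls of the real splits.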

How the results depend on the processing

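The alternatives without genes of RNAs lacking a poly(A) tail, with a Y gene covariate and with both replicate-3 thymocyte libraries left out, and camera on the interactions, were added after the data were seen. Where a value changed, the cause was not tested. Requiring at least a 2-fold change left 616 higher and 647 lower genes in the PNUTS knockout, 1929 and 741 in the LEO1 knockout, 725 and 982 in HEL, and 521 and 706 in CCRF-CEM. It left 1798 genes larger in LEO1 and 970 in PNUTS, 859 larger in HEL and 884 in CCRF-CEM, and 364 (K562), 214 (HEL and CCRF-CEM) and 34 (3 comparisons) shared calls. A replicate block gave 3670 and 3203 genes in the PNUTS set, and DESeq2 gave 1869 shared calls in HEL and CCRF-CEM, 692 in 3 comparisons and 1 lower gene in thymocytes. With an estimated correlation, 0 gene lists were called in each of the 5 comparisons and 0 structure lists in the PNUTS, LEO1 and thymocyte sets. With fry, 16, 27, 22, 19 and 0 gene lists were called in PNUTS, LEO1, HEL, CCRF-CEM and thymocytes, and 4, 3, 2 and 0 structure lists in LEO1, HEL, CCRF-CEM and thymocytes. Library totals gave 3 structure lists in PNUTS and 0 in LEO1, and a 1 CPM filter gave 4 in LEO1. Leaving out both replicate-3 libraries in thymocytes called 3 higher genes (Kdm5d, Uty and Ddx3y).

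Leaving out 1 library at a time gave 1252 to 1908 higher and 1433 to 2173 lower genes in PNUTS, 4579 to 4872 and 4526 to 4943 in LEO1, 3411 to 3764 and 3342 to 3754 in HEL, 2391 to 4097 and 2362 to 4107 in CCRF-CEM, and 0 to 4 and 0 to 8 in thymocytes. The 1252 came without control replicate 2 and the 2362 without shCtrl replicate 1. The 4 came without the library labelled WT replicate 3 (the Y genes Kdm5d, Uty, Eif2s3y and Ddx3y) and the 8 without cKO replicate 1 (Utp14b, Fam83d, Per1, Odc1, Dnajb9, Snx18, Sik1 and Dusp5), genes named after their values were seen. Gene lists ranged from 8 to 11, 11 to 12, 6 to 8, 8 to 9 and 8 to 15 in PNUTS, LEO1, HEL, CCRF-CEM and thymocytes, with 9 without WT replicate 2 and 8 without cKO replicate 3. Structure lists ranged from 1 to 3 in PNUTS, 0 to 3 in LEO1, 0 to 0 in HEL and CCRF-CEM and 1 to 3 in thymocytes. The interactions ranged from 3021 to 3679 (larger in LEO1), 2832 to 3716 (PNUTS), 2345 to 3322 (HEL) and 2304 to 2930 (CCRF-CEM).

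Directions turned only for results that had not passed, except 3 thymocyte lists. With 1 library left out at a time, the log2 fold change of PAF1 in the PNUTS set ran from −0.16 to 0.083. In thymocytes, that of Rtf1 ran from −0.12 to 0.013, Leo1 from −0.17 to 0.025, Ctr9 from −0.042 to 0.17 and Ppp1r10 from −0.086 to 0.14. With the Y gene covariate, Paf1 was 0.30, Wdr61 −0.078 and Ctr9 −0.13, and without both replicate-3 libraries Leo1 was 0.090 and Ppp1r10 −0.023. Camera adjusted p ran from 2.56e-18 to 0.879 for ribosomal proteins and from 1.55e-06 to 0.375 for oxidative phosphorylation, both turned without WT replicate 2, and from 0.00114 to 0.978 for DNA repair, turned without cKO replicate 3.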

Other observations

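The tests on lists for a difference between the K562 knockouts were chosen only after results were seen. In this test, 9 of 28 lists were called for LEO1 minus PNUTS, and interferon-stimulated genes alone were still called with an estimated correlation (adjusted p = 0.0209; camera adjusted p = 6.61e-05 at the preset value). Of these genes, OAS3 rose by 2.85 ± 0.09 and RSAD2 by 2.40 ± 0.10 in the LEO1 knockout, while IFITM1 fell in both knockouts. Autophagy and lysosome genes (0.0169) and myeloid and monocyte genes (0.0169) also lay higher in LEO1 relative to PNUTS, and DNA repair (0.000754), ribosome biogenesis and MYC targets (0.000467), G1/S (0.0169), heat shock (0.0193), Integrator subunits (0.0193) and cleavage and termination factors (0.0326) lower, each lost with an estimated correlation (adjusted p from 0.471 to 0.589).

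Some gene groups behaved alike across comparisons by their own tests. For the lists, differences were tested only between the 2 K562 knockouts and between HEL and CCRF-CEM. The integrated stress response list was called lower in the PNUTS, LEO1 and HEL comparisons, and each call was lost with an estimated correlation (adjusted p = 0.624, 0.309 and 0.584). The PNUTS call was also lost without knockout replicate 3 (0.0512). In CCRF-CEM the list's camera adjusted p was 0.848, and 8 genes rose and 8 fell. Tested directly, the list lay lower in HEL relative to CCRF-CEM (camera adjusted p = 0.00691), which was lost with an estimated correlation (adjusted p = 0.113). Between the LEO1 and PNUTS knockouts it did not pass (camera adjusted p = 0.0862). The cholesterol list was called lower in the same 3 comparisons, each lost with an estimated correlation (adjusted p = 0.624, 0.408 and 0.584), and had adjusted p = 0.569 in CCRF-CEM. The difference between HEL and CCRF-CEM in this list was lost as well (adjusted p = 0.113 with an estimated correlation). CTR9 rose in all 4 human comparisons, by 0.36 ± 0.11, 0.53 ± 0.04, 0.15 ± 0.05 and 0.70 ± 0.06 in the PNUTS, LEO1, HEL and CCRF-CEM sets, and PPP1R10 fell in all 4. The CTR9 call was lost in the PNUTS set with library totals (adjusted p = 0.0576) and without control replicate 2 (0.0891) or 3 (0.0949) or knockout replicate 1 (0.108) or 2 (0.166). In HEL it was lost with library totals (0.205), with DESeq2 (0.0853) and without shCtrl replicate 1 (0.0525) or shPAF1 replicate 1 (0.169). The PPP1R10 call was lost in the PNUTS set without control replicate 1 (0.105) or 3 (0.126) or knockout replicate 1 (0.0992) or 2 (0.147), and in HEL with library totals (0.517).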
